A study of Mus musculus with 9 samples.

How the data were processed

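ATAC-seq libraries came from mouse embryonic stem cells at 0, 1 and 2 h of 4OHT, with 3 libraries at each time, named A, B and C in the labels. The labels do not say whether the letters stand for separate cultures, so the authors' p-values measure the spread between these libraries, which may be technical. The description fields name the replicates differently: libraries titled B are tagged B2 there and libraries titled C are tagged B, so B and C may be repeats of the same replicate, which the labels do not settle. Each tag covers all 3 times, and no value within a tag could be computed because the table used here holds no values per library.

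The build mm10 and the tools Bowtie2, bedtools and MACS2 are named, without versions or roles, per the submitters' processing notes. The differential test, the read filters, the handling of Tn5 offsets and duplicates, and the depth per library are not given in the sources used here. The authors' deposited table gives each site's position and width, its mean level over all libraries, over control libraries and over 4OHT libraries as log2 normalized reads, and a log2 fold, per the file headers and the values. The authors' fold is control minus 4OHT, as it equals the difference of the levels to within 0.01, and its sign was turned here so that a positive log2 change means higher after 4OHT. The p-value and FDR of each site are the authors' deposited values, copied without refitting. The largest p-value was 7.9e-04 and the largest FDR 0.01, so the list is bounded by FDR. That the 4OHT side holds 6 libraries and the control side 3 was inferred from the levels: weights of 3 to 6 left a largest residual of 0.00986, and equal weights a median residual of 0.180. Of columns from other samples there were 0.

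Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49997 genes of which 21900 are protein-coding. That table gives a start and an end without strand, so the planned distance to transcription start sites was replaced by the distance of the site centre to either end of a gene (1 kb) and to the gene body. Exons, introns and UTRs were not told apart. Each site was given to the nearest protein-coding gene body, within 100 kb for the lists. The nearest gene is a naming convention and need not be the gene a site acts on. Of 203 distinct list genes, 202 were found in the gene table.

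Directions were compared with each other, since sites that did not pass are not in the list used here. A count adjusted over the list alone needs p-values of unlisted sites and was not computed. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only and treat sites as independent. Lists and gene features were tested with two-sided Fisher's exact tests, the 14 lists with Benjamini-Hochberg adjustment, and the size of change with a permutation test of 100000 resamples. Random gene sets matched in coarse bins of the number of sites (10000 draws, seed 11) served as a test with genes as units. They were not matched on level, gene length or the spacing of sites, and the list's own genes could be drawn. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

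Sites and genes named were fixed by rule before the data were examined. The rule takes the 10 sites with the largest change in each direction, up to 4 sites per direction and list with the smallest p (1 per gene), and the 5 genes per direction nearest to the most sites. Named in addition, after their values were seen, were sites with the smallest p outside that rule (the second Egr1 site, Jak1, the Baz2b site at 3.85, Slc2a2, Tet1, Zfhx4, Dennd1b and Erbb4) and further list members given as counts of sites.

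The tests were run on simulated directions, drawn independently for each of the real sites, in 200 simulations. With no effect, 3.89% of the list tests on the 16454 assigned sites had p under 0.05. Real neighbouring sites moved together, so the error rate of these tests under such clustering was not measured. A list set to 80% higher was called in 95.5% of simulations, and a gene-end odds ratio of 2 on the 19165 sites came back as 2.00. Alternatives were an FDR under 0.05, which removed no site, a stricter limit on the change, autosomes alone, other windows and distances, 1 site per gene, lists without gene-end sites, and, chosen after the data were seen, an FDR under 0.001, strata of level or feature, the nearest gene end, lists without their largest gene, random genes, and the mean level or the midpoint of both levels in place of the control level. Intervals for neighbouring sites come from 1000 bootstraps of 1 Mb blocks. The 24 planned motifs and the GC content of sites need a genome sequence, so neither was used. The planned test per library was not run either.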

Results

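Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse embryonic stem cells of the E14tg2a line. The cells stably expressed cRAF-ErT2, a RAF kinase fused to a modified estrogen receptor domain, so that 4-hydroxytamoxifen (4OHT) switches on ERK signalling. They were grown with LIF and 2 µM Chir99021, an inhibitor of GSK3. For the last 24 h they were moved to medium with serum, LIF and 250 nM PD173074, an inhibitor of FGF receptors. The growth protocol does not list Chir99021 for these last 24 h. Of the 9 libraries, 3 came from untreated cells (0 h), 3 from cells given 250 nM 4OHT for 1 h and 3 from cells given it for 2 h. The values used were those of the authors' deposited table of differentially accessible sites, which sets control libraries against 4OHT libraries and gives a mean for each side. The mean over all libraries in that table equalled a mean weighted 3 to 6, to within 0.00986 on the log2 scale at every site, so the 4OHT side was taken to pool 1 h and 2 h, and these times were not compared here. Read depth per library is unknown. The level behind a site, as the mean over the 9 libraries, had a median of 125 normalized reads, with quartiles of 63.1 and 280.

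The first question was which sites opened and which closed after 4OHT, given to switch on ERK through cRAF. No cells without the fusion and no vehicle-treated cells are among the 9 libraries. Effects of 4OHT itself or of handling therefore cannot be told apart from those of ERK. The authors' deposited table listed 19165 sites, all with an FDR of 0.01 or less, and accessibility was higher after 4OHT at 10079 of them and lower at 9086. Sites near Egr1, an immediate early transcription factor, and Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, had the smallest p-values among those that rose. Sites near Slc2a2, a glucose transporter gene, and Tet1, which encodes a 5-methylcytosine dioxygenase, had the smallest p-values among those that fell. The higher share was 52.6% of the listed sites (exact Clopper-Pearson 95% interval 51.9 to 53.3%). The table holds only sites that passed, and its FDR and p-values imply about 243800 sites tested if the FDR is that of Benjamini and Hochberg, of which the listed sites are 7.86%.

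Among the listed sites, gains were larger than losses. In the authors' deposited table, the median log2 change was 1.46 at sites that rose (quartiles 1.04 and 1.92), a 2.75-fold gain, and -0.94 at sites that fell (quartiles -1.15 and -0.76), a 1.92-fold loss. A log2 change of at least 1 in size was listed at 7819 higher sites (77.6%) and 3857 lower sites (42.4%), and one of at least 2 at 2195 higher and 18 lower sites. The difference in the median size of the change was 0.52 on the log2 scale (two-sided permutation test across sites, 100000 resamples, p = 1e-05, the smallest they can give). Sites are not independent replicates, and neighbouring sites moved together, so this p describes the list and not the spread between cultures. The median changes of higher and lower sites were 2.02 and -1.395 at mean log2 levels below 5, where 68.5% of sites were higher. They were 1.30 and -0.90 at levels of 7 to 8, and 0.55 and -0.56 at 10 and above. The list was cut by FDR, and how far this selection sets the difference in size was not tested.

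**Figure D1:**
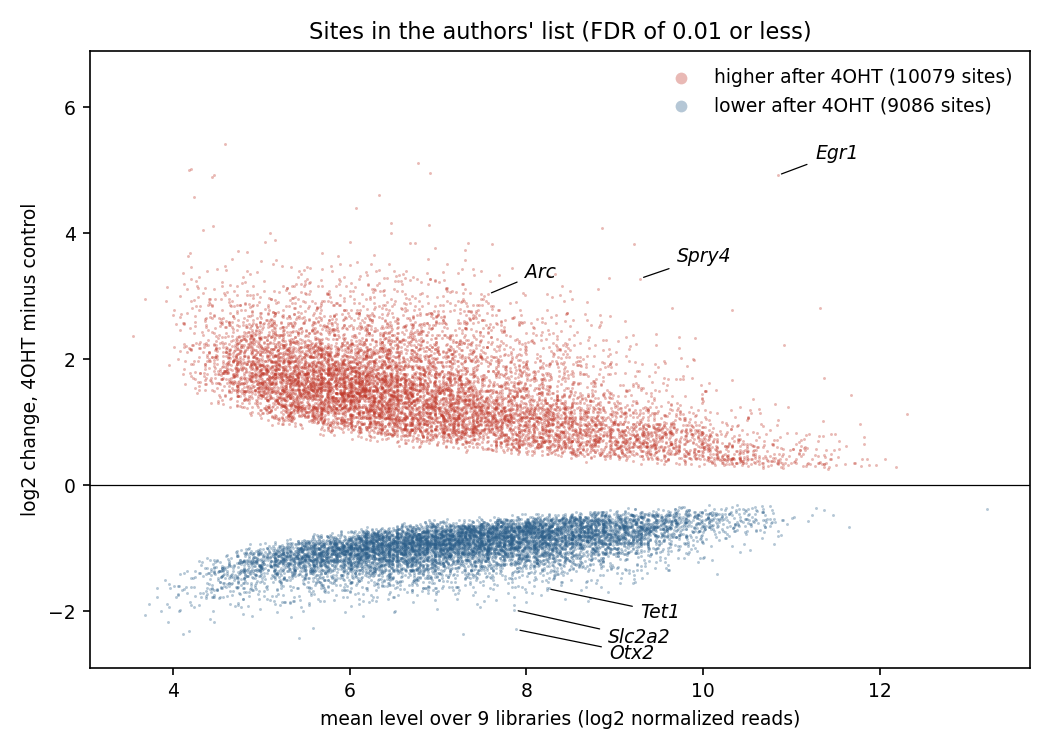
Each point is 1 of the 19165 listed sites, with its mean level over the 9 libraries (log2 normalized reads) on the x axis and the authors' log2 change, 4OHT minus control, on the y axis. Higher sites (red, 10079) reach a change of 5.42 and lower sites (blue, 9086) reach -2.43, and the smallest change listed is 0.26 in size.

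The site with the smallest p in the authors' deposited table overlapped the end of the Egr1 gene, with its centre 452 bp beyond it, at chromosome 18, 34864933 to 34865884 (mm10), and rose from 6.48 to 11.4 in log2 normalized reads. That is a log2 change of 4.92, or 30.3-fold, with the authors' FDR at 2.15e-103. A second site, inside Egr1 at 34862190 to 34864149, rose by 2.81 (FDR 4.28e-37). At Spry4, a site inside the gene at chromosome 18, 38586554 to 38587198, rose by 3.28, or 9.71-fold (FDR 4.37e-26). Sites inside Jak1, a cytokine receptor kinase gene, and Baz2b, a bromodomain gene, rose by 3.32 and 3.85, with FDR values of 3.97e-17 and 1.11e-16 in the authors' deposited table. Among the 10 sites with the largest gains were those nearest Arntl (5.42), Cyth4 (5.11), Iqsec3 (5.02), Bcl11b (5), Efr3b (4.96) and Med13l (4.93), as log2 changes. The log2 control levels in the authors' deposited table were lowest at the Arntl, Iqsec3 and Bcl11b sites, at -0.25 or 0.841 normalized reads. They were 0.10 at the Med13l site and at that nearest Nap1l3 (log2 change 4.89) and 0.23 at that nearest Tmem114 (4.57), so the folds of these 6 sites rest on a control level of about 1 normalized read.

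Among sites that fell, the one nearest Slc2a2, with its centre 20878 bp outside that gene at chromosome 3, 28748949 to 28749529, went from 8.86 to 6.88 in log2 normalized reads in the authors' deposited table (log2 change -1.98, FDR 6.34e-21). The one nearest Tet1, at chromosome 10, 62895510 to 62895823, had its centre 8197 bp outside the gene and changed by -1.64 (FDR 6.18e-18). Sites nearest Zfhx4, Dennd1b and Erbb4, which encodes a receptor tyrosine kinase, followed, at -1.08, -1.22 and -1.55. The largest losses in the authors' deposited table were nearest Cyp2d12 (-2.43), Wdr11 (-2.37), Zfp972 (-2.37), Zscan4d (-2.32) and Otx2 (-2.29). Cyp2d12, Zfp972 and Zscan4d belong to families of near-identical copies, and how reads that match several copies were handled is not given in the sources used here, so these 3 are uncertain. The Otx2 site, at chromosome 14, 48716507 to 48716964, had its centre 49091 bp outside this gene for a homeobox transcription factor of the epiblast and forebrain, and went from 8.97 to 6.68 (FDR 3.66e-04).

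Next, the direction of change was compared between 14 gene lists fixed before the data were examined. Of the listed sites, 16454 lay within 100 kb of a protein-coding gene body and were given to the nearest one, which covered 7907 genes. Sites near ERK feedback and FGF target genes rose more often than other sites when sites were counted, while tests with genes as units, given below, were divided. Of the 18 genes, 15 had a listed site, 8 with only higher sites, 1 with only lower sites and 6 with both. In all, 53 of their 63 sites were higher (84.1%, exact interval 72.7 to 92.1%) against 54.5% of other sites (odds ratio 4.42, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.82e-05). All 11 sites of Spry4, all 9 of Phlda1 and all 6 of Dusp5, a nuclear ERK phosphatase gene, were higher, with median log2 changes of 1.38, 2.02 and 1.80 in the authors' deposited table. The ETS factor genes Etv4 and Etv5 had 4 of 4 and 5 of 6 sites higher. Dusp6, a cytoplasmic ERK phosphatase gene, had 2 sites, both lower. The first by the authors' p had its centre 31527 bp outside the gene and changed by -0.84 (FDR 1.27e-07). Spred2 had 3 higher and 3 lower.

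Sites near ERK immediate early genes also rose more often when sites were counted, but the list did not pass with genes as units (adjusted p = 0.0602 against random gene sets, and 0.335 by Fisher's exact test with 1 site per gene). A site was listed for 20 of these 22 genes, of which 14 had only higher sites, 2 only lower sites and 4 both. Of their 51 sites, 40 were higher (78.4%, exact interval 64.7 to 88.7%, odds ratio 3.03, Fisher's exact test, adjusted p = 0.00414). In the authors' deposited table Arc, a neuronal activity gene, had a site inside the gene at chromosome 15, 74670150 to 74670348, that rose by 3.03 (FDR 1.17e-15), and all 5 of its sites were higher. Srf, the serum response factor gene, had 1 site, which rose by 1.2 (FDR 1.56e-08), and Klf6 had 7 higher and 1 lower. The genes with only lower sites were Ier5, with 4, and Egr4, with 2. The list did not pass the same exact test with changes of at least 1 (odds ratio 1.66, adjusted p = 0.406) or without gene-end sites (odds ratio 2.53, adjusted p = 0.0672).

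Sites of 1 gene are not independent of each other. Against 10000 random sets of genes, matched in coarse bins of the number of sites, the adjusted p of the feedback list was 0.0140. These sets were not matched on gene length or the spacing of sites. Closer sites moved together more often, so this p may be too small. With 1 site per gene, the one with the smallest p by the authors, the feedback list did not pass Fisher's exact test (adjusted p = 0.230). The kept site was higher at 13 of its 15 genes (odds ratio 4.84 against other genes). It was higher at 15 of the 20 immediate early genes (odds ratio 2.23).

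**Figure D2:**
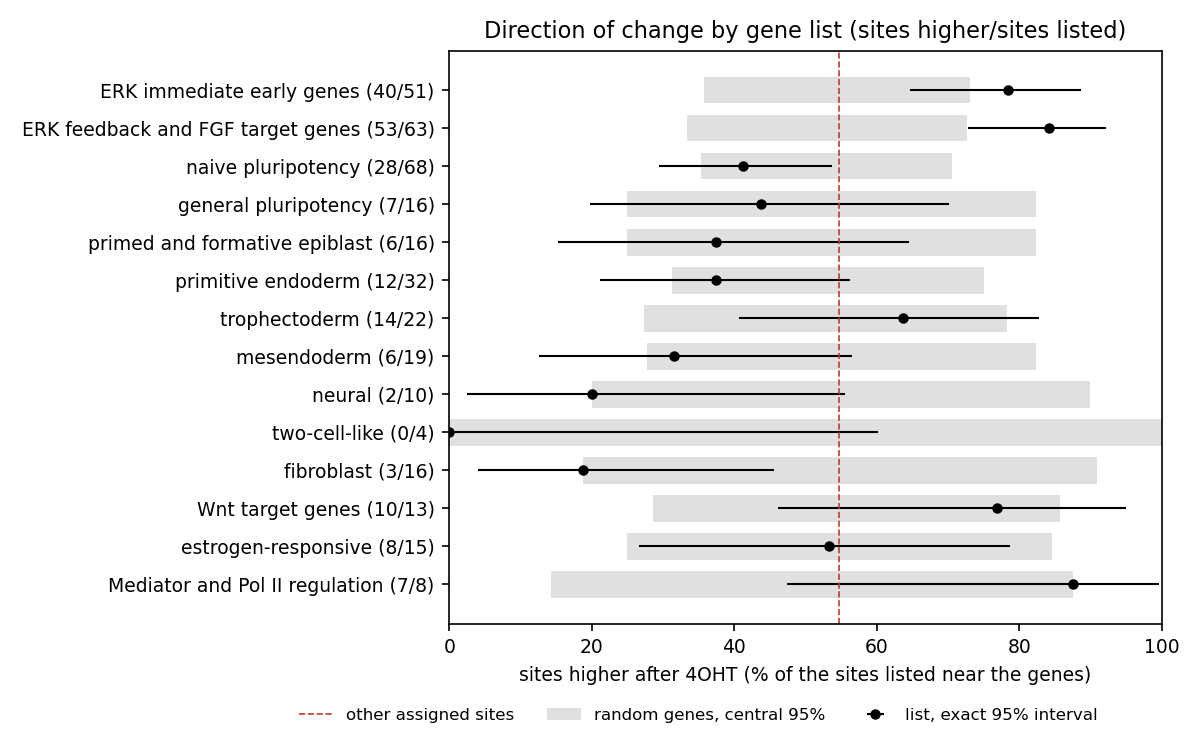
Share of listed sites that were higher after 4OHT (x axis, percent) for each of the 14 gene lists (y axis), with exact Clopper-Pearson 95% intervals, the higher and listed sites beside each name, the share of other sites as a dashed line and the central 95% of random gene sets in grey. The feedback list at 84.1% and the immediate early list at 78.4% lie highest among lists with over 20 sites, and the fibroblast list at 18.8% has 9 of its 13 lower sites at Fn1.

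Sites near naive pluripotency genes went both ways. Of 20 genes, 17 had a site, 8 with only lower sites, 2 with only higher sites and 7 with both. Of their sites, 28 were higher and 40 lower (41.2% higher, odds ratio 0.580), and the list did not pass Fisher's exact test after adjustment (adjusted p = 0.0978). It passed the same exact test within 50 kb (adjusted p = 0.0380) and without Nr5a2, the gene with the most sites (adjusted p = 0.0282), and in none of the other alternatives run, where the adjusted p reached 0.915 with FDR under 0.001. Against random gene sets its adjusted p was 0.312. With 1 site per gene, 5 genes had a higher and 12 a lower site (odds ratio 0.309, exact test, unadjusted p = 0.0257, adjusted p = 0.230). All listed sites were lower at Prdm14 (6), Tfcp2l1 (5), Socs3 (4), Fgf4 (2) and Dppa5a (2), and Nanog, Klf2 and Klf4 had 1 lower site each. All were higher at Klf5 (5) and Zfp42 (6). In the authors' deposited table a site inside Esrrb, a nuclear receptor gene of the naive state, changed by -1.26 (FDR 7.68e-10), and 1 inside Fgf4, the ligand gene of the pathway, changed by -0.71 (FDR 2.40e-07).

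None of the lists of lineage genes passed Fisher's exact test after adjustment. Primitive endoderm genes had 12 higher and 20 lower sites (37.5% higher, exact test, adjusted p = 0.124). Among them, Fgfr2 had 5 lower and 1 higher, the laminin gene Lamb1 had 3 lower, Gata6 had 1 lower, and Sparc had 4 higher. Mesendoderm genes had 6 higher and 13 lower sites (exact test, adjusted p = 0.124, and 0.0195 within 50 kb), of which Gsc held 6 of the lower ones. Primed and formative epiblast genes had 6 higher and 10 lower sites (exact test, adjusted p = 0.268), and all 5 sites of Otx2 were lower, without which the list had 6 higher and 5 lower. With 1 site per gene, the epiblast and trophectoderm lists had 4 higher and 4 lower sites each and the mesendoderm list 5 and 5. Neural genes had 2 higher and 8 lower sites (exact test, adjusted p = 0.119), and trophectoderm genes 14 higher and 8 lower (adjusted p = 0.562), with all 4 sites of Gata3 higher. General pluripotency genes, such as Pou5f1 and Sox2 with 1 higher site each, had 7 higher and 9 lower sites (exact test, adjusted p = 0.531).

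The lists for other cell types and other pathways gave 1 call. Fibroblast genes, for feeder cells, had 3 higher and 13 lower sites (18.8% higher, odds ratio 0.191, Fisher's exact test, adjusted p = 0.0217). Of the lower sites, 9 were at Fn1, the fibronectin gene, and without it the list had 3 higher and 4 lower sites (exact test, adjusted p = 0.902). Its adjusted p against random genes was 0.202, and by the exact test it was 0.399 with 1 site per gene, 0.0772 without gene-end sites and 0.0614 with FDR under 0.001. Two-cell-like genes had 4 sites, all lower (exact test, adjusted p = 0.118), and those of Zscan4d and Tcstv1 are uncertain because of near-identical copies. Estrogen-responsive genes, for effects of 4OHT itself, had 8 higher and 7 lower sites (exact test, adjusted p = 1). Wnt target genes, included because Chir99021 acts on this pathway, had 10 higher and 3 lower sites (exact test, adjusted p = 0.227). Mediator and RNA polymerase II genes had 7 higher and 1 lower (exact test, adjusted p = 0.124).

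Some genes held many sites that moved in the same direction. Jarid2, which encodes a cofactor of a Polycomb repressive complex, was nearest to 39 higher sites and 1 lower site, and 36 of the higher ones lay inside the gene, at chromosome 13, 44730774 to 44921643. Their median log2 change in the authors' deposited table was 1.16, with a range of 0.55 to 1.75. Nrp2, a neuropilin gene, had 25 higher and 0 lower sites, Map4k3 21 and 1, Map4k4 16 and 0, and Adam23 15 and 0. The genes with the most lower sites held higher ones as well. Magi1 had 16 lower and 5 higher sites, Auts2 14 and 5, Mgat5 14 and 1, Msi2 12 and 8, and Etl4 11 and 12. The 5 genes with the most higher sites are 115 to 191 kb long and the 5 with the most lower sites 283 to 1106 kb. A long gene can hold more sites, and whether the mixing of directions follows length was not tested.

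**Figure D3:**
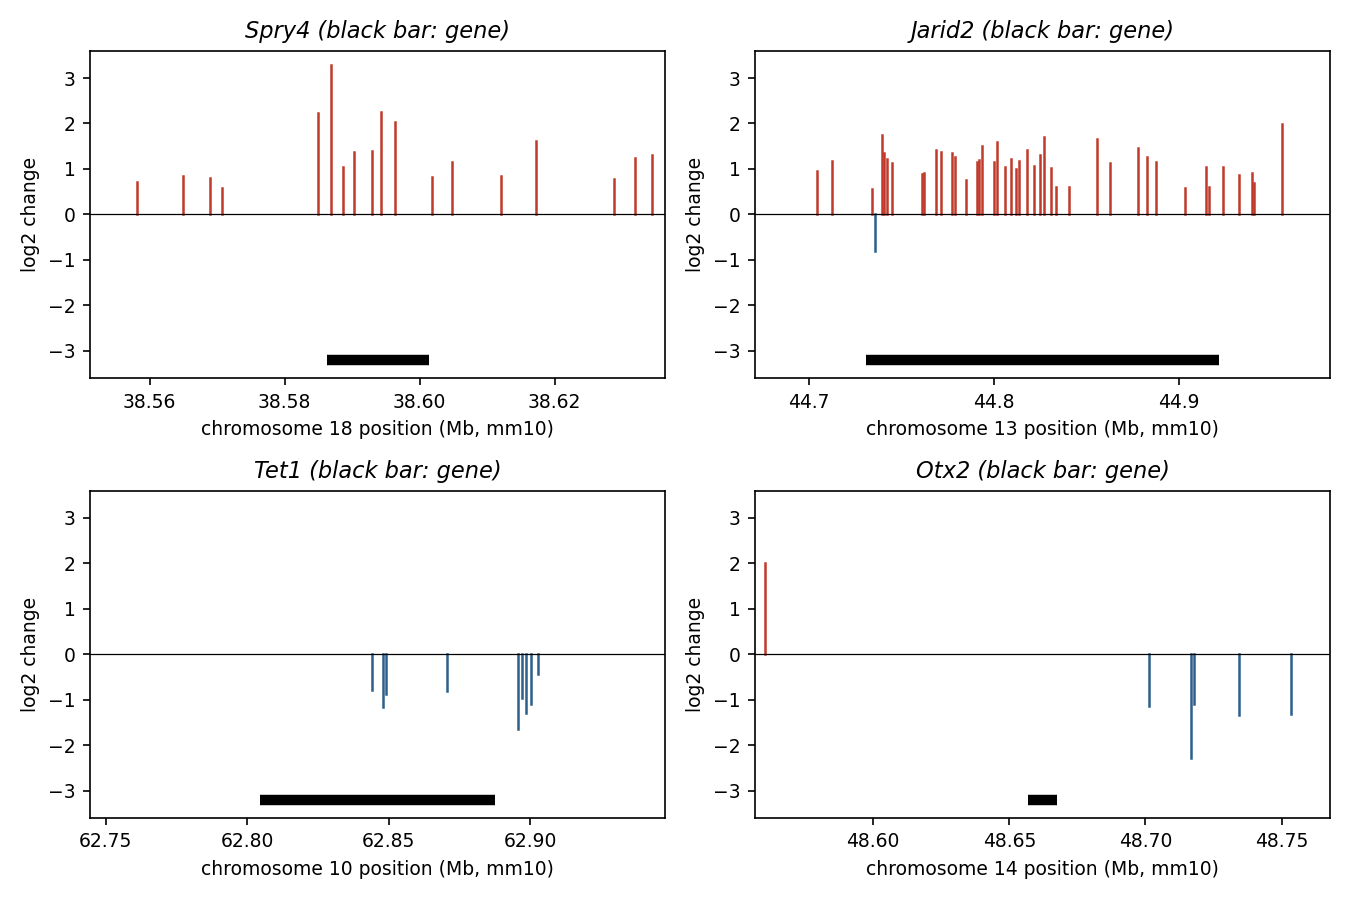
Listed sites around Spry4, Jarid2, Tet1 and Otx2, with the position in megabases (mm10) on the x axis, the authors' log2 change on the y axis and the gene as a black bar. All listed sites in each window are drawn, including those nearest to another gene, with higher sites in red and lower sites in blue.

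Sites that rose lay in or near genes more often than sites that fell. Within 1 kb of either end of an annotated gene were 1015 higher sites (10.1%, exact interval 9.49 to 10.7%) and 564 lower sites (6.21%, 5.72 to 6.72%), an odds ratio of 1.69 (two-sided Fisher's exact test, p = 1.45e-22). Inside a gene and away from its ends were 56.0% of higher and 49.3% of lower sites (odds ratio 1.31, Fisher's exact p = 2.01e-20), and outside genes 33.9% and 44.5%. The gene-end difference varied with the level of the site (Breslow-Day chi-square test of equal odds ratios over quintiles of the mean level, 19165 sites, p = 2.25e-19, chosen after the values were seen). In the quintile of sites with the highest mean level, 21.6% of higher sites and 6.44% of lower sites were near a gene end (odds ratio 4.01, Fisher's exact p = 1.34e-43). In the quintile with the lowest level the shares were 6.38% and 5.87% (odds ratio 1.09, Fisher's exact p = 0.570). With quintiles of the midpoint of the control and 4OHT levels, these odds ratios were 4.83 and 0.902. Strand was not used, so gene starts and gene ends were not told apart.

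**Figure D4:**
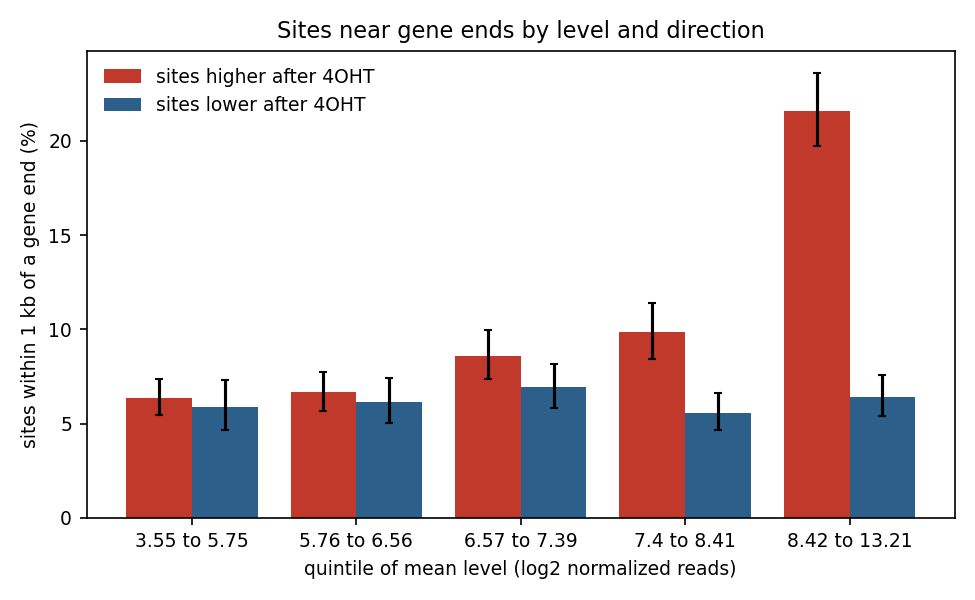
Share of sites within 1 kb of a gene end (y axis, percent) in each quintile of the mean level (x axis, log2 normalized reads), for higher (red) and lower (blue) sites, with exact Clopper-Pearson 95% intervals. The shares are 6.38% and 5.87% in the lowest quintile and 21.6% and 6.44% in the highest.

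Sites that rose started from a lower level. Their median control level was 5.43 in log2 normalized reads, against 7.83 at sites that fell, whereas the median 4OHT levels were 7 and 6.89. Higher sites were also narrower, with a median width of 408 bp against 557 bp. Across sites, Spearman's rho between the control level and the log2 change was -0.595 (permutation p = 1e-04, the smallest 10000 resamples can give). The control level also enters the change, and with the mean level in its place rho was -0.178 (permutation p = 5e-04, the smallest 2000 resamples can give). With the midpoint of the control and 4OHT log2 levels, which weighs both sides alike, rho was -0.337. The higher share was 68.5% at mean log2 levels below 5, fell to 40.3% between 8 and 9, and was 66.4% at 10 and above. The share at 10 and above depended on the level used, as the mean over 9 libraries weighs 4OHT more: it was 57.7% by the midpoint (exact interval 53.5 to 61.8%) and 32.2% by the control level (28.7 to 35.9%).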

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

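Tests chosen after the data were seen were the FDR under 0.001, the strata of level and of gene feature, the nearest gene end, the lists without their largest gene, the random genes and the mean level or midpoint in place of the control level. The limit of FDR under 0.05 removed no site and says nothing about stability. Without it, the 3 lists past the threshold lost their call in 10 of 36 alternatives and kept it in 26. Of all 191 alternative values, 163 kept their direction and their side of the threshold or stayed close to the reported value, most of them for lists that did not pass the main test. The gene-end odds ratio stayed above 1 and past its threshold in these alternatives, from 1.27 with changes of at least 1 to 2.42 with ends of protein-coding genes. Within single quintiles of the mean level it did not pass in the lowest ones (1.09, 1.09 and 1.26, Fisher's exact p = 0.570, 0.549 and 0.0538). It passed in the upper ones (1.85 and 4.01). The value pooled over the quintiles, 1.82, assumes a common odds ratio, which the Breslow-Day test went against. Depth is unknown, and the list does not show how many sites were too weak to pass.

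With changes of at least 1, the higher share was 67.0%, 3857 sites were lower, and the odds ratio of the immediate early list was 1.66. With FDR under 0.001, the higher share was 53.4%, with 4842 higher and 4224 lower sites, and the odds ratio of the fibroblast list was 0.0988. The number of lists past Fisher's exact test was 3, and it was 5 within 50 kb, 2 with changes of at least 1, 2 with FDR under 0.001, 1 without gene-end sites and 0 with 1 site per gene, where 2 lists (feedback and naive) had an unadjusted p under 0.05. By other tests it was 4 in strata of level (Mantel-Haenszel) and 1 against random genes. In the other alternatives it was 3, which without each list's largest gene were the feedback, immediate early and naive lists. With 1 site per gene the odds ratios were 2.23 for the immediate early, 4.84 for the feedback and 0.186 for the fibroblast list. Fewer sites are tested there. Without gene-end sites they were 2.53 for the immediate early and 0.217 for the fibroblast list, and the fibroblast list without Fn1 was at 0.622. Against random genes they were 3.23 for the immediate early and 0.231 for the fibroblast list. All list odds ratios in this paragraph lost their call with the same direction, and apart from the fewer sites the cause was not tested.

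Lists that did not pass came past the threshold in 4 cases, the naive list within 50 kb and without Nr5a2, the mesendoderm list within 50 kb and the two-cell-like list in strata of level, and they turned direction in 5. The trophectoderm odds ratio, 1.45, was 0.944 within 500 kb and 0.743 with 1 site per gene. The estrogen-responsive odds ratio, 0.949, was 3.12 with changes of at least 1, 1.39 without gene-end sites and 1.04 in strata of level. The cause was not tested. No paired analysis was possible because the table used here holds means and no values per library. For the same reason no library could be left out, and the planned tests per library and the planned motif tests were not run.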

Other observations

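The higher share differed between chromosomes when sites were counted as independent. On chromosome 19, 304 of 486 listed sites were higher (62.6%, two-sided Fisher's exact test against the other chromosomes, adjusted p = 1.62e-04), and on chromosome X 210 of 472 were (44.5%, adjusted p = 0.00402). No other chromosome passed. Neighbouring sites moved together, so these p-values may be too small, and level, gene features and GC content were not adjusted for. Beyond the fixed lists, sites nearest Ptprs, a receptor phosphatase gene, were all higher (13, median log2 change 1.67 in the authors' deposited table), as were those of Plec (11), Slc4a7 (11) and Ywhaz (10). Epha2, an ephrin receptor gene, had 10 higher sites and 1 lower. Tet1 and Fn1 had 9 sites each, all lower, with medians of -0.97 and -1.17 in the authors' deposited table. Rad51b had 10 lower and 1 higher. These genes were picked from the list after their values were seen.

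The tests below on neighbouring sites and on sites at a log2 level of 10 or more were chosen after the pattern was seen, except the comparison of pairs inside and across gene ends, whose outcome was stated before its result. The margin of 5 percentage points for reading that comparison was set afterwards. Adjacent listed sites moved the same way in 91.1% of pairs up to 1 kb apart, 73.3% at 5 to 10 kb, 62.0% at 10 to 25 kb and 54.2% at 100 to 1000 kb.

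Up to 5 kb apart, 81.2% of 1716 pairs moved the same way, against at most 54.0% in 1000 shuffles of direction within chromosomes, which argues against chance placement. The share fell by 19.2 points (95% block bootstrap interval 16.5 to 21.7) between gaps up to 5 kb and gaps of 10 to 25 kb, which argues against copy number differences in segments longer than 25 kb as the whole cause. For pairs 5 to 25 kb apart, the excess over chance was 13.9 points (11.4 to 16.4) where both sites lay outside protein-coding genes, which argues against change along such gene bodies as the whole cause, and it was 14.7 points inside the same gene and 17.9 across a gene end. The difference between the last 2 was -3.23 points (-7.60 to 0.646), and a part from gene bodies would make it positive. The interval reaches above 0, so such a part is not excluded. Its upper limit is small beside the 14.7 points inside the same gene. Any such part would thus be small if other causes act alike on both kinds of pair. Shorter copy number segments would leave the difference at 0, so it alone cannot exclude them. However, the libraries came from 1 cell line, treated for at most 2 h. Median changes were a 2.75-fold gain at 10079 sites and a 1.92-fold loss at 9086 sites. Changes of this size in both directions argue against copy number differences, short or long, that arose in that time. Differences already present between cultures before treatment were not tested. At 25 to 50 kb apart, 59.4% of pairs still moved the same way (exact interval 57.5 to 61.2%, at most 53.5% in shuffles). This argues against peaks split from 1 region narrower than 25 kb as the whole cause. The widest listed site was 3382 bp, but that does not bound the region that several peaks came from, so wider regions stay open. Regional differences between libraries in GC content or background were not tested. That ERK may act on domains with several sites also stays an untested hypothesis.

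Higher sites started from a lower control level than lower sites and were narrower. A lower signal-to-noise ratio in the 4OHT libraries could raise weak sites and lower strong ones. Among sites at a log2 level of 10 or more, 57.7% were higher by the midpoint of the control and 4OHT levels (exact interval 53.5 to 61.8%), which goes against it, but 32.2% were by the control level (28.7 to 35.9%), which enters the change and so favours lower sites. As the answer turns with the level used, this explanation stays open, as do differences in depth and the selection of sites by FDR, which could not be tested without values per library. No biological explanation was tested for this pattern of levels.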
